A study of Mus musculus with 1152 samples.

How the data were processed

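The series holds microglia, the resident macrophages of the brain, sorted one cell to a well and sequenced with Smart-seq2, a full-length protocol without molecular identifiers. The cells came from cortex, hippocampus and cerebellum of wild-type (WT) C57BL/6J mice and of 5xFAD mice, a transgenic line that forms amyloid plaques. The labels give C57BL/6J for the 5xFAD mice as well. Per the labels, sorting used CD11b, CD45, Ly6C, Ly6G and CD206 antibodies. The 1152 wells lay on 3 plates, and 12 of them were blanks. WT cortex and WT hippocampus shared plate 209, WT cerebellum and 5xFAD cortex shared plate 210, and 5xFAD hippocampus and 5xFAD cerebellum shared plate 211.

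The deposited table held raw counts, reads per gene and well, with 48587 genes and 92 ERCC spike-ins. Per the submitters' processing notes, reads were aligned to GRCm38 with STAR 2.5.2b and counted with featureCounts 1.5.1; the annotation, trimming and filters are not given in the sources used here. No normalization had been applied to the deposited counts. In 96 deposited columns, those of wells in plate columns 1 and 2, each value was a sum over several wells: the column of well 1 of a plate row also held wells 10 to 19 of that plate row, and the column of well 2 also held wells 20 to 24. Subtracting the other wells gave 0 negative values among 4673184, whereas subtracting the wells of the next plate row gave 506416. Median genes detected in these columns was 8859 as deposited and 2085 after subtraction, against 2562 in the other wells. The recovered counts were used throughout, and 68 of these wells passed the cell filter.

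A well was kept with at least 500 genes, at least 10000 reads in genes and at most 20% of its reads on mitochondrially encoded genes. This kept 1041 of 1140 wells labelled as cells and dropped 99. The blanks had 130 to 279 genes and 3109 to 8422 reads in genes. Median depth of the kept cells per group ran from 198492 to 343580 reads in genes. The mouse, not the cell, was the replicate: counts were summed over the kept cells of each mouse and region, which gave 22 sums of 35 to 72 cells and 5696201 to 26669220 reads. Because reads of 1 molecule are not independent, floors and intervals cover counting error only. The floor against a group at 0 was 3 counts over the group.

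Differential expression used edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr (17358 genes tested), 1 quasi-likelihood fit of all 22 sums with a term per group, and Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05. Fold changes are log2. In the edgeR fits their standard error (SE) is derived from the test, as the absolute fold change over the square root of its F statistic. Levels are log2 CPM (reads scaled to the library size) of the sums with their standard deviation (SD). Each group lay on 1 plate, so plate could not be a term. Within a genotype the replicate number was taken to mark the mouse, since the series states that the regions came from the same mice. This pairing is an assumption. The number left no trace in the counts: after group means were removed, correlations over 6591 genes between regions of the same mouse ran from -0.0368 to 0.0343 over 21 pairs, with a median of -0.005 and 0 above 0.1. A fit with mouse as a block was among the alternatives. Across genotypes the numbers pair nothing.

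Gene lists of 14 programs and 10 other cell types were fixed before the data were examined, as were the groups, tests, alternatives and the rule for named genes, apart from the alternatives given here as chosen later. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists of a comparison. Member counts are given over all genes tested and adjusted over the list alone. Some lists share members, so their tests and counts are not independent. Among others, Ctsb, Ctsd, Ctsl, Ctsz, Cd68 and Npc2 are on both the disease-associated microglia and the lysosome list. Of the disease-associated list, Trem2 and Tyrobp are also complement and phagocytic receptors, Lpl, Ch25h and Npc2 lipid handling genes and B2m a MHC class I gene. Camera compares a list with the other genes, so its direction can differ from the sign of the median. Setting genes of a group at 0 to their bound left each list median printed for a comparison of 2 groups at the same 2 decimals.

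The named genes of 5 comparisons (5xFAD against WT in each region, hippocampus against cerebellum in 5xFAD, hippocampus against cortex in WT) were the 8 higher and 8 lower with the largest fold change among those past the threshold, with a mean log2 CPM of at least 4, a read in at least 20% of the cells of one group and mouse values that did not overlap; predicted, ribosomal and mitochondrial genes were left out. Up to 4 members of each list with the smallest p were added, and P2ry12, Tmem119, Cx3cr1, Apoe, Trem2, Cst7 and 1 more gene, which is not reported here, always. Genes named outside this rule were chosen after their values were seen; they are those of the other region comparisons and of the combined contrasts, and those named as members in passing. Coordinates are those of GENCODE M21 on GRCm38, in which 177 of the 178 named genes had 1 locus.

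For a share of cells, each kept cell was thinned to 53000 reads and counted as panel-positive with a read in at least 3 of 8 genes of the disease-associated program (Cst7, Clec7a, Itgax, Spp1, Lpl, Axl, Igf1, Gpnmb). This left 939 cells; shallower cells were not used. Shares per mouse were compared with exact permutation tests. The panel score is not a cell type. None of the blanks was positive (0 of 12) and 3 had a read in a panel gene, but at 3109 to 8422 reads they do not show the background at 53000 reads.

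The alternatives set at the start were DESeq2 1.42.0, its size factors in the edgeR fit, no filter on low counts, only genes detected in at least 10% of the cells of a group, limma on the mean log2(CPM + 1) of cells, limma voom with mouse as a random effect, no cell filter, a stricter filter (1000 genes and 50000 reads), thinned cells, only the groups compared in the fit, mouse as a block, cells of clusters led by other cell types left out, other panel minimums and each replicate left out. The columns as deposited, the wells of plate columns 1 and 2 left out, and the list tests under other settings were chosen after seeing the data. Clusters came from scanpy 1.11.5 with leidenalg 0.10.2. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest. The gene test was tested on simulated data: counts with 200 changed genes gave 55, 42 and 37 calls with 1, 0 and 0 false calls for genotype in cortex, hippocampus and cerebellum. For hippocampus against cerebellum in 5xFAD, hippocampus against cortex in WT and the difference in genotype effect between hippocampus and cerebellum there were 37, 42 and 31 calls with 0, 4 and 1 false calls. Of simulated changes of 4 log2 units at a mean log2 CPM of at least 4, 78.95% were called in cerebellum, and of those of 1 log2 unit 5.263%. The simulated counts held no plate, mouse or cell-type effect and no correlation between genes. Of their genes 13948 to 14001 passed the filter, fewer than in the data. These rates therefore need not hold for the real sums. Xist was present in all 22 sums (415.5 to 1529 CPM) and 4 Y-linked genes together did not exceed 0.4571 CPM, as in female mice; the labels do not state the sex.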

Results

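Transcripts of 1140 single sorted microglia were counted, from 5xFAD and WT mice. After filtering, WT cortex, hippocampus and cerebellum gave 167, 182 and 162 cells from 4 mice each. The 5xFAD cortex gave 183 cells from 4 mice, hippocampus 154 cells from 3 mice and cerebellum 193 cells from 3 mice. Median depth per cell was lowest in WT cortex, at 198492 reads in genes, and highest in 5xFAD cerebellum, at 343580. Median genes detected per cell ran from 2388 in WT cerebellum to 2909.5 in 5xFAD hippocampus. The design asks how amyloid pathology changes microglia in each region and how microglia of the regions differ within a genotype.

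The first comparison was 5xFAD against WT in cortex (4 mice each). The list of disease-associated microglia genes was higher as a set in 5xFAD cortex, while the homeostatic receptor gene P2ry12 fell. The lysosome and MHC class I lists, which share members with the disease-associated list, were higher too. Lpl, lipoprotein lipase (chromosome 8, 68880491 to 68907448), rose by a log2 fold change of 6.79 ± 1.10 (SE), from 0.45 ± 1.54 (SD, n = 4) to 7.62 ± 0.54 log2 CPM (SD, n = 4). Hcar2, a receptor for hydroxybutyrate (chromosome 5, 123863570 to 123865499), rose by 6.98 ± 1.45 and was detected in 25.1% of 5xFAD cells against 0.599% of WT cells. The cathepsin gene Ctsb (chromosome 14, 63122462 to 63145923) rose by 0.90 ± 0.10 and the MHC class I gene H2-D1 (chromosome 17, 35262730 to 35267499) by 1.48 ± 0.17. P2ry12, a purinergic receptor of resting microglia (chromosome 3, 59216272 to 59262871), fell by 0.50 ± 0.08.

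Of 17358 genes tested in cortex, 51 passed an adjusted p of 0.05 (edgeR), 42 higher and 9 lower in 5xFAD, and the mouse values of the groups did not overlap for any of the 51. Over all genes, 5.715% did not overlap, where chance gives 2.86%. Other genes that rose were Myo1e (3.59 ± 0.72), an unconventional myosin, Ank (3.01 ± 0.58), a pyrophosphate transporter, the actin-capping gene Capg (2.17 ± 0.41), Lgals3bp (1.92 ± 0.31), which encodes a galectin-binding glycoprotein, and Aplp2 (1.67 ± 0.31), an APP-like gene. Ch25h, cholesterol 25-hydroxylase, had 2199 reads in 5xFAD and 3 in WT cortex, a ratio of 478 after scaling to depth (95% exact counting interval 163 to 2320, adjusted p = 0.00898). Genes that fell included the crystallin gene Crybb1 (-1.18 ± 0.24), the sialomucin gene Cd164 (-0.81 ± 0.15), the nuclear non-coding RNA Malat1 (-0.77 ± 0.11) and Rgs2 (-0.66 ± 0.13), a regulator of G protein signalling. Slc34a2, a phosphate transporter gene (chromosome 5, 53038081 to 53071664), fell by a log2 fold change of -2.14 ± 0.15; this gene also made up 77.96% of the gene reads of the blank wells.

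**Figure D1:**
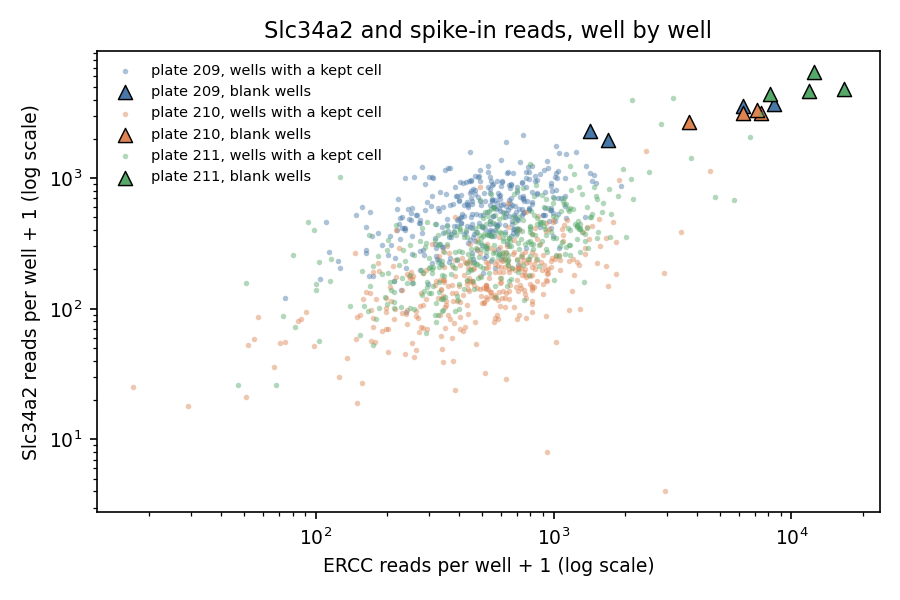
Slc34a2 reads against ERCC reads in the kept wells and the blanks. The lowest Spearman rho of the 6 groups, per gene read, is 0.426.

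Cx3cr1 and Tmem119 had adjusted p of 0.71 and 0.392.

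Of the 45 genes of the disease-associated microglia program, 19 rose in cortex, 0 fell and 26 did not pass. When adjusted over the list alone 35 rose, and the median log2 fold change was 1.04 (camera adjusted p = 9.39e-60 and 5.22e-06). Of each pair of adjusted p for a list, the second comes with an estimated correlation. The members Ctsz (0.87 ± 0.12), Ctsd (0.93 ± 0.13) and Cd68 (0.87 ± 0.12), a lysosomal membrane marker of phagocytes, rose, whereas Cst7, a cystatin, had 6.16 ± 1.45 with an adjusted p of 0.0857. The lysosome list had 11 of 39 higher and 0 lower (18 higher adjusted over the list alone, median 0.31, adjusted p = 7.67e-22 and 0.000517), among them the progranulin gene Grn (0.63 ± 0.11). MHC class I had 4 of 17 higher (6 adjusted over the list alone, median 0.80, adjusted p = 6.57e-18 and 0.000353), with B2m at 0.80 ± 0.11, H2-K1 at 1.35 ± 0.21 and H2-T23 at 1.02 ± 0.19. Complement and phagocytic receptors had 2 of 24 higher, Trem2 (0.61 ± 0.10) and its adaptor Tyrobp (0.77 ± 0.15), and 10 adjusted over the list alone (median 0.33, adjusted p = 2.36e-08 and 6.20e-05). Lipid handling had 4 of 29 higher (9 adjusted over the list alone, median 0.83, adjusted p = 1.21e-14 and 6.20e-05), including the receptor gene Lrp1 (0.83 ± 0.15) and the sterol carrier gene Npc2 (0.71 ± 0.15). Of the Alzheimer risk loci, 3 of 32 rose, Trem2, Ctsb and Grn (6 higher and 1 lower adjusted over the list alone, median 0.14, adjusted p = 0.00203 and 0.016). Their call with an estimated correlation was lost with the stricter filter, with thinned cells, in the columns as deposited and without the wells of plate columns 1 and 2 (adjusted p = 0.0721, 0.0672, 0.0522 and 0.0539).

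The interferon response list was higher as a set in 5xFAD cortex (32 of 33 positive, median 1.15, adjusted p = 1.21e-14 and 0.0298). It had 0 members passing over all genes and 1 adjusted over the list alone. Ifi27l2a had 3.31 ± 0.79 (adjusted p = 0.0908). Inflammatory cytokines and chemokines were higher as a set too (0 of 28 passing, 8 adjusted over the list alone, median 1.13, adjusted p = 1.62e-08 and 0.0231), and the chemokine gene Ccl4 had 7.01 ± 1.76 (adjusted p = 0.115). Homeostatic microglia genes had 1 of 29 higher, Serinc3 (0.63 ± 0.08), and 2 lower, P2ry12 and Crybb1 (2 higher and 4 lower adjusted over the list alone, median -0.10, adjusted p = 0.011), and the set's call was lost with an estimated correlation (adjusted p = 0.127). Glycolysis (0 of 18 passing, 1 higher adjusted over the list alone, median 0.42, adjusted p = 0.000628) and immediate early genes (0 of 23 passing, 6 adjusted over the list alone, median 0.38, adjusted p = 0.00547) lost their calls as well (adjusted p = 0.0709 and 0.0839 with an estimated correlation). Other settings changed some of these calls. With an estimated correlation, interferon response lost its call with thinned cells, in the columns as deposited and without the wells of plate columns 1 and 2 (adjusted p = 0.0531, 0.0522 and 0.0672). Inflammatory genes lost theirs in the first and last of these (adjusted p = 0.0501 and 0.0539). Homeostatic genes gained it in 4 settings (smallest adjusted p = 0.0215), immediate early genes in 2 (0.0425) and glycolysis in 1 (0.0199). At the preset correlation homeostatic genes did not pass without a filter on low counts, nor immediate early genes with the stricter filter (adjusted p = 0.16 and 0.0556). The cell cycle list (0 of 26, median -0.53, adjusted p = 0.404) did not pass. MHC class II (0 of 9, median -0.41, mean -1.21, test direction up, adjusted p = 0.396) and the cerebellar clearance program (0 of 13, 2 higher adjusted over the list alone, median -0.25, mean -0.31, test direction up, adjusted p = 0.0858) did not pass either. Both were moved by 1 well of WT mouse 1, in a cluster led by markers of other cell types. Without that cluster both passed, with medians of 1.47 and 1.70. In the other settings the medians ran from -0.45 to 0.05 and from -0.43 to 0.03, and the clearance program also passed with mouse as a block (adjusted p = 0.045) and in the columns as deposited (adjusted p = 0.0044, lost at 0.2415 with an estimated correlation). Apoe, the apolipoprotein E gene (chromosome 7, 19696109 to 19699188), went from 2.97 ± 0.89 (adjusted p = 0.261) to 4.92 ± 0.63 and passed.

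WT and 5xFAD cortex lay on different plates, so genotype and plate cannot be told apart here. The number of genes passing in cortex ran from 25 with only these groups in the fit to 557 with limma on cell means, and was 33 and 29 without 5xFAD mouse 2 and 3 and 32 without either WT mouse 3 or 4.

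The same comparison in hippocampus (3 5xFAD and 4 WT mice) gave larger numbers. Cst7 (chromosome 2, 150570415 to 150578944) rose by 8.06 ± 1.59, from 1.03 ± 3.07 (SD, n = 4) to 10.86 ± 0.43 log2 CPM (SD, n = 3), and was detected in 66.2% of 5xFAD cells against 3.85% of WT cells. Apoe rose by 5.08 ± 1.00, Lpl by 6.76 ± 1.08 and Axl, a receptor tyrosine kinase for apoptotic cells (chromosome 7, 25757273 to 25788705), by 5.60 ± 1.34. Ch25h (chromosome 19, 34473778 to 34475164) had 5424 reads in 5xFAD and 0 in WT hippocampus and was at least 1560-fold higher. Bhlhe40, a transcription factor gene (chromosome 6, 108660629 to 108666925), was at least 906-fold higher. The growth factor gene Igf1 (chromosome 10, 87858265 to 87937042) had 5913 reads against 1, a ratio of 5110 after scaling to depth (95% exact counting interval 916 to 202000).

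In hippocampus 176 of 17358 genes passed (edgeR), 132 higher and 44 lower in 5xFAD, all 176 without overlap between the mice of the groups. Over all genes 11.009% did not overlap, where chance gives 5.71%. The inhibitory receptor genes Lilrb4a (5.32 ± 1.13) and Cd72 (5.25 ± 1.18) were among those that rose. Those that fell included Gp9 (-2.75 ± 0.66), a platelet glycoprotein gene, the tetraspanin gene Tspan18 (-2.49 ± 0.55), and the histamine-degrading enzyme gene Hnmt (-2.17 ± 0.41). They also included the glucocorticoid-induced gene Tsc22d3 (-2.15 ± 0.45), Crybb1 (-2.06 ± 0.28), the iron exporter gene Slc40a1 (-1.69 ± 0.35), Zfp691 (-1.67 ± 0.41) and the chromatin remodeller gene Chd2 (-1.63 ± 0.39).

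Of the 45 disease-associated microglia genes, 32 rose in hippocampus and 13 did not pass. When adjusted over the list alone 43 rose, and all 45 had a positive fold change (median 1.97, adjusted p = 6.55e-97 and 1.43e-07). Ctsb rose by 1.69 ± 0.10 and Ctsd by 1.54 ± 0.14. Homeostatic microglia genes fell as a set (7 of 29 lower and 1 higher, and 15 lower and 1 higher adjusted over the list alone, median -0.37, adjusted p = 2.07e-13 and 0.000338). P2ry12 was at -1.07 ± 0.09, Tmem119 at -0.80 ± 0.14, Selplg, the P-selectin ligand gene, at -0.72 ± 0.09 and the fractalkine receptor gene Cx3cr1 at -0.37 ± 0.09. The member that rose was Serinc3. The lysosome list had 19 of 39 higher (26 higher and 1 lower adjusted over the list alone, median 0.70, adjusted p = 2.62e-35 and 5.75e-05). Glycolysis had 5 of 18 higher (10 adjusted over the list alone, median 1.10, adjusted p = 5.35e-13 and 0.000896). Tpi1, triosephosphate isomerase, was at 2.16 ± 0.30 and Hif1a, the hypoxia-inducible factor gene, at 1.96 ± 0.30. Lipid handling had 5 of 29 higher (12 higher and 1 lower adjusted over the list alone, median 1.30, adjusted p = 5.35e-13 and 5.75e-05), including Lpl, Apoe, Npc2 and the lipid droplet coat gene Plin2 (2.57 ± 0.45). Complement and phagocytic receptors had 6 of 24 higher, among them Tyrobp (1.59 ± 0.16), Trem2 (0.82 ± 0.11) and the Fc receptor gene Fcgr2b (0.88 ± 0.15), and 1 lower, the scavenger receptor gene Stab1 (-1.08 ± 0.21). For this list 10 were higher and 1 lower adjusted over the list alone (median 0.37, adjusted p = 1.64e-06 and 0.000191). MHC class I had 3 of 17 higher, H2-D1 (2.23 ± 0.18), H2-K1 (1.62 ± 0.23) and B2m (1.27 ± 0.12), and 8 adjusted over the list alone (median 0.83, adjusted p = 3.33e-16 and 0.000338).

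Interferon response genes were higher as a set in 5xFAD hippocampus (2 of 33 passing, 5 adjusted over the list alone, median 1.90, adjusted p = 7.35e-15 and 0.03). The members that rose were Ifi27l2a (4.66 ± 0.86) and Slfn5, at least 448-fold higher. Inflammatory cytokines and chemokines had 1 of 28 higher, the maturation marker gene Cd83 (1.09 ± 0.26), and 7 adjusted over the list alone (median 1.13, adjusted p = 0.000211), and the set's call was lost with an estimated correlation (adjusted p = 0.0968). The Alzheimer risk loci had 6 of 32 higher, among them Grn (0.87 ± 0.12), Ctsh (0.95 ± 0.15) and Apoe, and 1 lower, Bin1. Adjusted over the list alone there were 6 higher and 2 lower (median 0.03, adjusted p = 0.0296), and this call was lost too (adjusted p = 0.056 with an estimated correlation). It was gained with an estimated correlation in 4 settings (smallest adjusted p = 0.0145), and lost at the preset one without a filter on low counts and in the columns as deposited (adjusted p = 0.275 and 0.081). Immediate early genes (0 of 23, 3 higher adjusted over the list alone, median 0.10, adjusted p = 0.228) and the cell cycle list (0 of 26, median 0.95, adjusted p = 0.346) did not pass. At the preset correlation alone the former passed with thinned cells and the latter in the columns as deposited (adjusted p = 0.0478 and 0.00938). MHC class II (0 of 9, median -0.66, adjusted p = 0.935) did not pass. Nor did the cerebellar clearance program (2 of 13 higher, Apoe and Axl, and 1 lower, Stab1, the same over the list alone, median -0.66, mean -0.47, test direction up, adjusted p = 0.346). They were moved by 1 well of WT mouse 3, in the cluster led by other cell types. Without that cluster both passed, with medians of 0.20 (call lost with an estimated correlation) and 2.78. In the other settings the medians ran from -0.69 to 0.72 and from -0.69 to 0.79, the upper ends in the columns as deposited, where the clearance program passed too (adjusted p = 0.0307, lost at 0.384 with an estimated correlation). Genotype and plate cannot be told apart in hippocampus either, and the count of 176 became 115 and 113 without 5xFAD mouse 1 and 2, 858 with DESeq2, 509 with limma on cell means, 362 with voom and 327 without a filter on low counts.

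The cortical and hippocampal comparisons share no sums. They are not independent, since the regions came from the same mice and both WT groups lay on the same plate. Of the genes that rose, 37 rose in both, where independent draws would share 0.319. Of those that fell, 7 fell in both, where independent draws would share 0.0228. Independent draws allow for neither the shared mice nor the shared plate. Of the 51 cortical genes, 49 had the same sign in hippocampus. Ctsb, Ctsd, Ctsz, Cd68, Trem2, Lpl and Ch25h were among the shared genes that rose, and P2ry12, Crybb1, Malat1 and Slc34a2 among those that fell.

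Marker lists of 10 other cell types did not pass in any of the 3 genotype comparisons. In cortex the medians were -2.84 for neurons (adjusted p = 0.193), -1.31 for astrocytes (0.242) and 7.66 for T and NK cells (0.259, 1 gene tested). Macrophages at brain borders (-0.43), monocytes (-1.47), neutrophils (-4.11), B cells (-1.61), oligodendrocytes (0.44), endothelial cells (-0.60) and red blood cells (-0.16) had an adjusted p of 0.803 each. The smallest adjusted p was 0.384 in hippocampus (monocytes, median 3.57) and 0.311 in cerebellum (neutrophils, median 7.70). Of the single markers, Csf3r of neutrophils and Trf of oligodendrocytes rose in hippocampus.

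**Figure D2:**
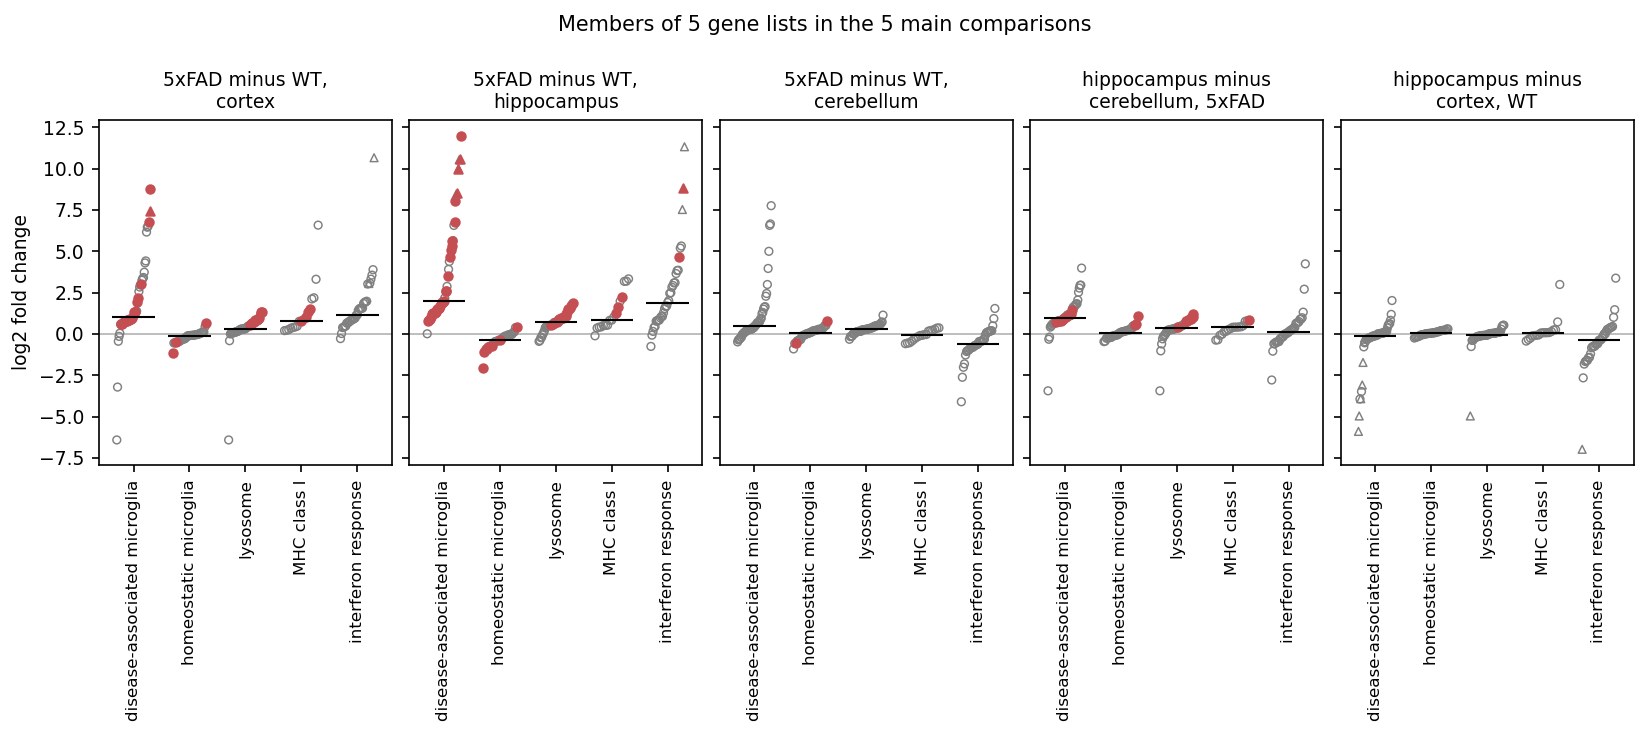
Log2 fold changes of the members of 5 gene lists in the 5 named comparisons; each point is a gene, filled where its adjusted p is under 0.05, triangles are bounds against a group at 0, and the line is the list's median. The disease-associated microglia list sits highest in 5xFAD against WT hippocampus, with a median of 1.97.

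In cerebellum (3 5xFAD and 4 WT mice) few genes differed between the genotypes. Serinc3, a membrane serine incorporator gene (chromosome 2, 163623272 to 163645131), rose by 0.77 ± 0.09, from 11.43 ± 0.13 (SD, n = 4) to 12.20 ± 0.06 log2 CPM (SD, n = 3). The cochaperone gene Dnajc7 (chromosome 11, 100582818 to 100620168) rose by 1.20 ± 0.22 and the pleckstrin gene Plek by 0.87 ± 0.16. Dock8, a guanine nucleotide exchange factor gene (chromosome 19, 24999534 to 25202432), fell by 0.95 ± 0.16, the RNA helicase gene Ddx5 by 0.66 ± 0.10 and the cystatin C gene Cst3 by 0.56 ± 0.10. Apoe was at -0.05 ± 0.89 and Trem2 at 0.06 ± 0.11 (adjusted p = 1.00 and 0.976). With limma on cell means Apoe was at 2.35 ± 0.51 and passed (adjusted p = 0.026). The cluster led by markers of other cell types had a mean Apoe of 26690 CPM in 5xFAD and 52000 CPM in WT cerebellum, and the other cells 2795 and 666.4 CPM. Without that cluster the fold change was 2.00 ± 0.58 (adjusted p = 0.401).

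In cerebellum 8 of 17358 genes passed (edgeR), 5 higher and 3 lower in 5xFAD, and 7.219% of all genes did not overlap between the mice, where chance gives 5.71%. Of the 45 disease-associated microglia genes 0 passed (3 higher adjusted over the list alone, 38 positive, median 0.46, adjusted p = 1.79e-05), and the set's call was lost with an estimated correlation (adjusted p = 0.17). The lysosome list had 0 of 39 passing (7 higher adjusted over the list alone, median 0.28, adjusted p = 1.93e-07). The cell cycle list had 0 of 26 (24 positive, median 2.18, adjusted p = 7.69e-09). Both calls were lost (adjusted p = 0.108 and 0.0801 with an estimated correlation). They held with it without a filter on low counts (adjusted p = 0.0212 for both), and for the cell cycle list with thinned cells (adjusted p = 0.0445). Of the 4 wells of 5xFAD cerebellum with at least 6 genes of dividing cells, 3 came from mouse 3, lay in the cluster led by other cell types and had 9 or 10 neutrophil markers. Psap, the prosaposin gene, had 0.59 ± 0.13 (adjusted p = 0.123). Glycolysis (0 of 18, 1 higher adjusted over the list alone, median 0.26, adjusted p = 0.0336) and immediate early genes (0 of 23, median 0.25, adjusted p = 0.0336) lost theirs as well (adjusted p = 0.361 and 0.333 with an estimated correlation). At the preset correlation they also lost them in 5 and 4 settings (adjusted p up to 0.214 and 0.383). Homeostatic microglia genes had 1 of 29 higher, Serinc3, and 1 lower, Cst3 (7 higher and 3 lower adjusted over the list alone, median 0.07, adjusted p = 0.665). No member passed in the other lists, whose adjusted p were 0.0961 for interferon response (median -0.61), 0.369 for MHC class I (median -0.09), and 0.335 for MHC class II (median -0.57). They were 0.884 for complement and phagocytic receptors (median -0.02, mean 0.23, test direction down), 0.108 for lipid handling (median 0.27) and 0.108 for inflammatory cytokines and chemokines (median 0.24). They were 0.852 for the Alzheimer risk loci (median 0.03, 1 higher adjusted over the list alone) and 0.852 for the clearance program (median -0.10, mean -0.39, test direction up). At the preset correlation alone some lists passed in other settings. These were homeostatic genes (adjusted p = 0.0247) and lipid handling (adjusted p = 0.023) without a filter on low counts, lipid handling without the cluster led by other cell types (adjusted p = 0.0265), and interferon response with the stricter filter and thinned cells (adjusted p = 0.0207 and 0.0499). Genotype and plate cannot be told apart in cerebellum. The 8 genes became 1 without 5xFAD mouse 3 or WT mouse 1, 2 without 5xFAD mouse 1 or WT mouse 2 or 3, 0 with only these groups in the fit and 391 with DESeq2. In all, 1549 genes had an unadjusted p under 0.05.

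The share of cells positive for the panel of 8 disease-associated genes was highest in 5xFAD hippocampus. It was 57.8% ± 7.86 (SD, n = 3) there and 0.568% ± 1.14 (SD, n = 4) in WT hippocampus (exact permutation p = 0.0286, the smallest that 35 splits can give). In cortex it was 28.4% ± 5.78 (SD, n = 4) in 5xFAD and 0.962% ± 1.92 (SD, n = 4) in WT (exact p = 0.0286). In cerebellum it was 16.9% ± 9.28 (SD, n = 3) in 5xFAD and 7.14% ± 5.05 (SD, n = 4) in WT, a difference of 9.78 points that did not pass (exact p = 0.143). That difference was 11.2 points with at least 4 genes required (exact p = 0.0286), 15.5 points with at least 2 (exact p = 0.114), -2.96 points in the columns as deposited (exact p = 0.943) and 5.53 points without 5xFAD mouse 1 (exact p = 0.333). The shares include cells of the cluster led by markers of other cell types, and were not computed without them. That cluster held 21 of 193 kept cells of 5xFAD cerebellum and 13 of 162 of WT cerebellum. Mean Axl, a panel gene, was 986.4 and 1185 CPM in these cells and 203.1 and 90.72 CPM in the others. Each group lay on 1 plate, so genotype and plate cannot be told apart in the differences of this share between genotypes. Within 5xFAD, on a single plate, the 40.9 points between hippocampus and cerebellum had an exact p of 0.1, the smallest that 3 mice against 3 allow. With the differences taken within each mouse (exact sign flips), p was 0.25, the smallest that 8 flips allow.

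**Figure D3:**
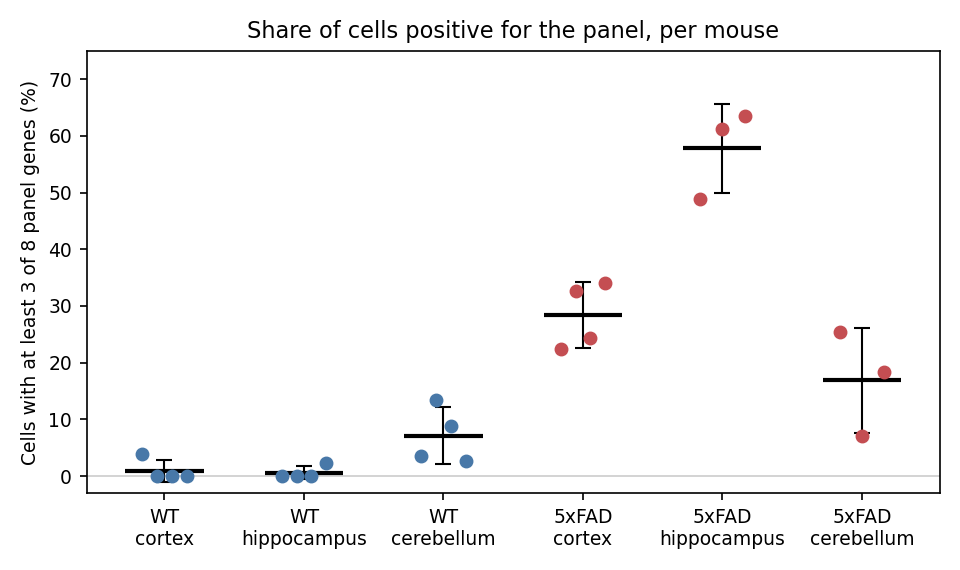
Percent of cells per mouse with at least 3 of the 8 panel genes after thinning to 53000 reads, by genotype and region; points are mice and bars are means with SD. The 5xFAD hippocampus lies at 57.8% and WT cortex and hippocampus lie below 1%. Each group lay on 1 plate.

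Hippocampus was compared with cerebellum in 5xFAD on a single plate (3 mice each). Tyrobp (chromosome 7, 30413760 to 30417585) was higher in hippocampus by 1.42 ± 0.17, at 11.37 ± 0.26 log2 CPM (SD, n = 3) against 9.93 ± 0.38 (SD, n = 3). The cathepsin D gene Ctsd (chromosome 7, 142375911 to 142388038) was higher by 1.23 ± 0.15, Trem2 (chromosome 17, 48346401 to 48354147) by 0.73 ± 0.12 and Fcrls, an Fc receptor-like gene of microglia (chromosome 3, 87250758 to 87263738), by 1.11 ± 0.11. Tgfbi, an extracellular matrix gene (chromosome 13, 56609523 to 56639562), was lower in hippocampus by a log2 fold change of -2.29 ± 0.47.

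In this comparison 38 of 17358 genes passed (edgeR), 36 higher and 2 lower in hippocampus. Of all genes, 13.561% did not overlap, where chance gives 10%. Other genes that passed were Serpine2 (1.53 ± 0.25), a protease inhibitor gene, Lag3 (1.40 ± 0.30), an inhibitory receptor gene, and Pld3 (1.37 ± 0.28), a lysosomal nuclease gene. So did the aldolase gene Aldoa (1.22 ± 0.20), the metalloprotease inhibitor gene Timp2 (1.17 ± 0.22) and, lower in hippocampus, the lysophosphatidic acid receptor gene Lpar6 (-1.05 ± 0.22). Disease-associated microglia genes had 11 of 45 higher (24 adjusted over the list alone, 42 positive, median 0.99, adjusted p = 4.41e-36 and 4.67e-05), among them Ctsb (0.90 ± 0.11), Ctsl (1.05 ± 0.15) and B2m (0.84 ± 0.13). The lysosome list had 8 of 39 higher (17 higher and 1 lower adjusted over the list alone, median 0.35, adjusted p = 5.65e-15 and 0.00582). Complement and phagocytic receptors had 3 of 24 higher, Trem2, Tyrobp and C1qb (10 higher and 1 lower adjusted over the list alone, median 0.17, mean -0.03, test direction up, adjusted p = 0.00266 and 0.0122). Homeostatic microglia genes had 3 of 29 higher, Fcrls, Cst3 (0.62 ± 0.10) and Sparc (0.52 ± 0.11), the same over the list alone, and the set did not pass (median 0.08, adjusted p = 0.154). MHC class I (1 of 17, B2m, also over the list alone, median 0.40, adjusted p = 0.00376), lipid handling (1 of 29, Npc2, also over the list alone, median 0.72, adjusted p = 0.00286) and glycolysis (1 of 18, Aldoa, 4 higher and 1 lower over the list alone, median 0.62, adjusted p = 0.000202) were higher as sets at the preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.141, 0.0628 and 0.0628). Lipid handling kept its call with it in 4 other settings (smallest adjusted p = 0.0115) and glycolysis in 3 (0.0125). In the columns as deposited and without a filter on low counts, the lysosome list (adjusted p = 0.267 and 0.0654) and complement and phagocytic receptors (adjusted p = 0.267 and 0.138) lost their calls with an estimated correlation. Without that filter the latter, MHC class I and lipid handling also lost the call at the preset correlation (adjusted p = 0.0563, 0.0552 and 0.0525), and with the stricter filter homeostatic genes gained it (adjusted p = 0.0241).

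MHC class II (0 of 9 passing, 2 lower adjusted over the list alone, median -3.52, adjusted p = 0.00181) was lower in hippocampus than in cerebellum. So was the cerebellar clearance program (0 of 13, 4 lower adjusted over the list alone, median -1.18, adjusted p = 0.000204). Both calls were lost with an estimated correlation (adjusted p = 0.14 for each). Markers of macrophages at brain borders moved with them (0 of 10 passing, 4 lower adjusted over the list alone, median -5.54, adjusted p = 2.11e-06 and 0.28). The cluster led by markers of other cell types held 21 of the 193 cells of 5xFAD cerebellum and 0 of the 154 of hippocampus. Without it the medians of the MHC class II and clearance lists were 0.34 and 0.30 and neither passed (adjusted p = 0.383 and 0.353, the largest over the settings tried, the smallest were 0.00174 and 0.000191). The cell cycle list (0 of 26, median -1.12, adjusted p = 0.000939) lost its call with an estimated correlation (adjusted p = 0.14) and, without that cluster, at the preset one (adjusted p = 0.439). Other lists did not pass. These were interferon response (0 of 33, median 0.10, mean 0.24, test direction down, adjusted p = 0.815) and inflammatory genes (0 of 28, median 0.18, adjusted p = 0.944). They were also immediate early genes (0 of 23, median 0.08, adjusted p = 0.515) and the Alzheimer risk loci (2 of 32 higher, 3 adjusted over the list alone, median -0.002, mean -0.16, test direction up, adjusted p = 0.304, and 0.0307 with the stricter filter). The 38 genes became 12 and 7 without the cerebellum of mouse 2 and 3 and 18 and 16 without the hippocampus of mouse 1 and 2, 0 in the columns as deposited, 5 with only these groups in the fit and 394 with DESeq2.

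Hippocampus was compared with cortex in WT mice, also on a single plate (4 mice each). P2ry12 was at 13.20 ± 0.14 log2 CPM (SD, n = 4) in hippocampus and 13.10 ± 0.09 (SD, n = 4) in cortex and Apoe at 7.86 ± 1.72 and 8.23 ± 1.91. With edgeR 0 of 17358 genes passed, while 1827 had an unadjusted p under 0.05; 3.099% of all genes did not overlap, where chance gives 2.86%. The counts were 384 with DESeq2, 43 without a filter on low counts, 11 with limma on cell means, 5 with voom, 5 with mouse as a block and 2 without the cortex of mouse 3. The smallest adjusted p of the fit were 0.474, among them those of the osteonectin gene Sparc (0.30 ± 0.09), the integrin gene Itgam (0.55 ± 0.16), the phosphofructokinase gene Pfkp (222 reads in cortex and 0 in hippocampus) and Tpi1 (-1.05 ± 0.28). None of the 14 program lists passed (smallest adjusted p = 0.117, glycolysis with a median of -0.20 and immediate early genes with 0.33). In other settings some passed at the preset correlation, each lost with an estimated one. These were glycolysis with the stricter filter, thinned cells and without the wells of plate columns 1 and 2 (adjusted p = 0.0068, 0.0107 and 0.0432), and immediate early and homeostatic genes without a filter on low counts (adjusted p = 0.0171 and 0.00755). They were also interferon response in the columns as deposited and the lysosome list with thinned cells (adjusted p = 0.0339 and 0.0441). Medians were 0.04 for homeostatic, -0.12 for disease-associated, -0.39 for interferon response, 0.07 for MHC class I, -0.19 for MHC class II (mean -0.41, test direction up), -0.07 for lysosome and 0.03 for lipid handling genes (mean -0.08, test direction up). The other medians were 0.07 for complement and phagocytic receptors, 0.27 for inflammatory genes, -0.71 for the cell cycle, -0.04 for the Alzheimer risk loci and -0.23 for the clearance program (mean 0.24, test direction up). Adjusted over the list alone, 1 interferon response gene (Slfn5) and 2 glycolysis genes (Pfkp and Tpi1) were lower in hippocampus.

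Cerebellum of WT mice differed more from the other WT regions, across plates. Against cortex 48 genes passed (edgeR, 26 higher and 22 lower in cerebellum, and 26 in all with mouse as a block), and hippocampus against cerebellum gave 65 (32 higher and 33 lower in hippocampus). Fcrls was lower in cerebellum than in cortex by a log2 fold change of -1.50 ± 0.10 and P2ry12 by -1.15 ± 0.08, and against cerebellum the hippocampus was higher by 1.54 ± 0.10 and 1.25 ± 0.08. H2-D1 was higher in cerebellum than in cortex by 1.32 ± 0.16. Homeostatic microglia genes were lower in cerebellum than in cortex (7 of 29 lower, 19 adjusted over the list alone, median -0.42, adjusted p = 3.80e-18 and 0.000262). Interferon response genes were higher there (1 of 33, 4 adjusted over the list alone, median 1.83, adjusted p = 2.18e-22 and 0.00803, the latter 0.0503 without the wells of plate columns 1 and 2). So were disease-associated microglia genes (3 of 45 higher, 14 higher and 1 lower adjusted over the list alone, median 0.57, adjusted p = 3.24e-12 and 0.00803). MHC class II genes were higher in cerebellum too (1 of 9, also over the list alone, median 2.19, adjusted p = 1.06e-05 and 0.0366). The cluster led by markers of other cell types held 13 of 162 cells in WT cerebellum and 1 of 167 in WT cortex. Without it the median was 0.96 and 0 of 9 passed (adjusted p = 5.43e-05 and 0.0137). The call with an estimated correlation was lost with the stricter filter, with thinned cells and without the wells of plate columns 1 and 2 (adjusted p = 0.11, 0.152 and 0.055). The cerebellar clearance program had a median of 2.24 in WT cerebellum against cortex. Without that cluster its median was 2.32, with 10 of 12 genes positive and 1 passing (adjusted p = 1.73e-05 and 0.00148). With the cluster kept, the same 3 settings gave the program an adjusted p of 0.11, 0.137 and 0.106 with an estimated correlation. Region and plate cannot be told apart in these comparisons. The count of 65 became 41 without the cerebellum of mouse 2 or the hippocampus of mouse 1, and 39 without the hippocampus of mouse 2.

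Within 5xFAD, cerebellum against cortex gave 10 genes (edgeR, 1 higher and 9 lower, and 4 in all with mouse as a block), and hippocampus against cortex gave 6 (5 higher and 1 lower). Fcrls (-1.16 ± 0.11), Cst3 (-0.76 ± 0.10), Tyrobp (-0.93 ± 0.16), Cd68 (-0.72 ± 0.13) and Lag3 (-1.53 ± 0.28) were lower in cerebellum than in cortex. Ctsb was higher in hippocampus than in cortex (0.67 ± 0.10) and Hnmt lower (-2.32 ± 0.41). Disease-associated microglia genes were higher in hippocampus than in cortex (1 of 45 passing, 14 adjusted over the list alone, 45 positive, median 0.71, adjusted p = 1.31e-17 and 0.00549, the latter 0.612 in the columns as deposited). Region and plate cannot be told apart here either. The cluster led by markers of other cell types held 21 of 193 cells in 5xFAD cerebellum and 0 of 183 in cortex, and without it the count of 10 became 3. That count became 3 and 2 without the cerebellum of mouse 2 and 3, and 3, 2, 2 and 4 without the cortex of mouse 1, 2, 3 and 4; that of 6 became 3 without the cortex of mouse 4.

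Adding the genotype effects of cortex and cerebellum and taking away that of hippocampus cancels plate terms that add on the log scale, and equals the genotype effect where the 3 regions share 1. This contrast gave 12 genes (edgeR, 2 higher and 10 lower). Those higher were Serinc3 (1.00 ± 0.15) and P2ry12 (0.88 ± 0.15). P2ry12 had fallen in cortex and hippocampus, comparisons across plates. Its measured genotype effects also differed between the regions, across plates, so its value here need not be a genotype effect. Those lower were predicted genes or unnamed transcripts. The count was 1 and 6 without the 5xFAD cerebellum of mouse 2 and 3, 7 and 6 without the 5xFAD hippocampus of mouse 1 and 2, 7 without the 5xFAD cortex of mouse 3 and 7 without the WT cortex of mouse 1. It was 0 in the columns as deposited, 0 with thinned cells and 500 with DESeq2. The genotype effect differed between hippocampus and cerebellum for 52 genes and between cortex and cerebellum for 14 (edgeR), across plates that these differences do not cancel. The 52 became 19 and 18 without the 5xFAD cerebellum of mouse 2 and 3, 29 and 18 without the 5xFAD hippocampus of mouse 1 and 2, 32 without the WT cerebellum of mouse 2, and 31 and 34 without the WT hippocampus of mouse 2 and 3. The 14 became 8 without the 5xFAD cerebellum of mouse 2 or 3 and 9 without the 5xFAD cortex of mouse 3. For P2ry12 the difference was -1.38 ± 0.13 in the first and -0.81 ± 0.12 in the second, and for H2-D1 2.06 ± 0.25 and 1.31 ± 0.24. Disease-associated microglia genes, which passed as a set in cortex and hippocampus and lost the call in cerebellum, had a median difference of 1.85 between hippocampus and cerebellum (adjusted p = 2.26e-45 and 9.85e-06) and of 0.84 between cortex and cerebellum.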

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

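The tests of explanations, the counts of splits for the 9 comparisons of 2 groups, the splits that respect the mouse, the restriction of the outlier check to named genes with a mean log2 CPM of at least 4 and the comparison of 5xFAD cortex with WT cerebellum on their shared plate were chosen only after the results were seen.

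Slc34a2 was lower in 5xFAD cortex than in WT cortex, and it made up 77.96% of the gene reads of the blank wells, which no comparison uses. Over the wells of each group, Slc34a2 reads went up with ERCC spike-in reads per gene read, with a Spearman rho of at least 0.426 in all 6 groups, so reads that come with the reagents rather than the cell may make up much of the signal. Depth as the whole cause is argued against by the ratio of Slc34a2 to ERCC reads, which does not depend on depth and was 2.91 times higher in WT cortex than in 5xFAD cortex. Genotype as the whole cause is argued against by WT cerebellum, which was below WT cortex by a log2 fold change of -1.57. The groups of a plate lay next to each other in this ratio, as a difference between the plates would give. Its median was 1.023 in WT cortex and 1.222 in WT hippocampus. It was 0.352 in 5xFAD cortex and 0.2645 in WT cerebellum, and 0.5419 in 5xFAD hippocampus and 0.5229 in 5xFAD cerebellum. In the blanks it ran from 0.4346 to 1.606 on the plate of WT cortex. On the plate of 5xFAD cortex it ran from 0.4207 to 0.7217. These ranges overlap, so whether the reagents differed between the plates stays open.

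Interferon response genes were lower in WT cortex and WT hippocampus than in the other 4 groups. These groups share a plate, and a plate difference cannot be told apart from the groups: of the 3 comparisons within a plate, the list's median farthest from 0 was -0.52, in 5xFAD cortex against WT cerebellum (adjusted p = 0.00441, and 0.335 with an estimated correlation). Without the cluster led by other cell types, the lower of the list's medians for 5xFAD against WT in cortex and hippocampus was 1.14. This could hardly have fallen, since that cluster held 0 cells of these 5xFAD groups and 1 of each WT group. In WT cerebellum against WT cortex the median was 1.69 without it (camera adjusted p = 6.07e-16 and 0.0283). For that comparison this argues against wells of other cell types as the whole cause. Genotype as the whole cause is argued against by WT cerebellum against WT cortex, with a median of 1.83. A difference between regions within WT that 5xFAD lacks stays open as well.

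Disease-associated microglia genes were higher in 5xFAD than in WT hippocampus. A plate difference cannot be told apart from genotype. In the combination of the 3 regions that cancels plates the list's median was -0.372 (adjusted p = 0.0333, and 0.662 with an estimated correlation), which differences between plates and regions alone would allow. With cells thinned to 1 depth the median was 2.31. Thinning keeps the proportions of the reads on average, so the median could hardly have fallen and this does not decide about depth. It also left out 21 of 154 cells of 5xFAD hippocampus and 5 of 182 of WT hippocampus as shallower. A response to the genotype stays open, and so does how much of the median of 1.97 comes from the plates.

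Splits of the same mice into groups of the same sizes were counted for each number of genes past the threshold. For 5xFAD against WT only the real split, 1 of 35, gave as many genes, the smallest share that 35 splits can give. This was so in cortex (51 genes, highest other split 0), hippocampus (176, highest other 13) and cerebellum (8, highest other 2). These shares were not adjusted over the comparisons, and the real split parts plates as well as genotypes. Within a genotype the mice gave a sum to both regions, except 5xFAD mouse 4, which gave cortex only. Only splits that part the 2 sums of each mouse with both compare with the real one, and these are too few to exclude chance. They were 8 for cerebellum against cortex in WT (48 genes, highest other 2), hippocampus against cerebellum in WT (65, highest other 4) and hippocampus against cortex in WT (0, highest other 2). They were also 8 for cerebellum against cortex (10, highest other 0) and hippocampus against cortex (6, highest other 0) in 5xFAD, and 4 for hippocampus against cerebellum in 5xFAD (38, highest other 0). Over all 35 splits, or 10 in the last, which ignore the mouse, the highest others were 5, 4, 2, 1, 0 and 0.

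For the combined contrasts whole mice were moved between the genotypes. Only 1 of 35 splits, the real one, gave as many genes for the combination that cancels plates (12 genes, highest other 0). The same held for the difference in genotype effect between cortex and cerebellum (14, highest other 2) and between hippocampus and cerebellum (52, highest other 3). The other splits mix the genotypes, so a genotype or plate difference common to the regions adds to their spread. They therefore do not exclude chance for these contrasts. With each region split on its own, which ignores the mouse, 1 of 100 splits (highest other 10), 3 of 99 (highest other 25) and 2 of 96 (highest other 59) gave as many genes. In the last 2, the splits with more genes kept the mice of cortex or hippocampus grouped as they were and mixed those of cerebellum.

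The genotype effect differed between hippocampus and cerebellum for 52 genes and between cortex and cerebellum for 14 (edgeR), each by a test of the difference itself, across plates. Between hippocampus and cerebellum the differences of named genes were -1.38 ± 0.13 (SE) for P2ry12, 1.61 ± 0.17 for B2m, 1.96 ± 0.23 for Tyrobp, 2.06 ± 0.25 for H2-D1, 1.21 ± 0.15 for Ctsb, -1.59 ± 0.23 for Slc34a2, 1.20 ± 0.18 for Ctsz, 1.41 ± 0.23 for Npc2, 1.17 ± 0.19 for Ctsd and 1.10 ± 0.20 for Ctsl. They were also 12.27 ± 2.22 for Ch25h (a fitted value, with 0 reads in WT hippocampus), -2.44 ± 0.48 for Slc40a1, 0.77 ± 0.15 for Trem2, 2.32 ± 0.47 for Lgals3bp, -1.11 ± 0.22 for Cd164, 2.14 ± 0.43 for Tpi1 and 1.41 ± 0.29 for H2-T23. List medians differed by -0.42 for homeostatic microglia, 1.85 for disease-associated microglia, 2.84 for interferon response, 1.07 for MHC class I, 0.38 for complement and phagocytic receptors, 0.53 for lysosome, 0.78 for lipid handling and 0.59 for glycolysis genes (largest adjusted p with an estimated correlation 0.0459, glycolysis); the median over all genes was 0.135.

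Between cortex and cerebellum the differences were -2.47 ± 0.22 for Slc34a2, 0.94 ± 0.14 for Ddx5, 1.13 ± 0.17 for B2m, -0.81 ± 0.12 for P2ry12, 1.29 ± 0.22 for Dock8, 1.62 ± 0.29 for H2-T23, 1.31 ± 0.24 for H2-D1 and 1.13 ± 0.22 for Tyrobp. List medians differed by 0.84 for disease-associated microglia, 1.13 for MHC class I, 0.39 for complement and phagocytic receptors and 0.59 for lipid handling genes (largest adjusted p with an estimated correlation 0.00513, lipid handling).

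In groups of 4 mice, 1 mouse lay far from the other 3 in 31 of 568 checks, where chance gives about 1 in 20 (28.4). The gap to the nearest mouse over the whole range is given for all but 1. In WT cerebellum it was 0.835 for Abcg1, 0.916 for Apoe, 0.889 for Bst2, 0.835 for Cd164, 0.844 for Crybb1, 0.952 for Ctsh, 0.860 for Dnajc7, 0.878 for Lag3, 0.858 for Pkm and 0.890 for the mean of the clearance program. In WT cortex it was 0.902 for Grn, 0.905 for H2-Ab1, 0.921 for Hnmt, 0.918 for Myo1e, 0.872 for Ptk2b, 0.869 for Sp100, 0.884 for median genes per cell, 0.892 for the mean of the homeostatic list and 1.0 for the share of panel cells, which 1 positive cell of 26 fixes. In WT hippocampus it was 0.925 for Cst3, 0.878 for Fcrls, 0.869 for Lag3, 0.871 for the mean of MHC class I, 0.938 for the mean of the clearance program and 1.0 for the share of panel cells, which 1 positive cell of 44 fixes. These 2 shares do not show that a mouse lay apart. In 5xFAD cortex it was 0.945 for Cst3, 0.978 for Ctsh, 0.835 for Fcgr2b, 0.958 for H2-Aa and 0.838 for Ifi27l2a.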

How the results depend on the processing

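The columns as deposited, the wells of plate columns 1 and 2 left out, and the list tests under other settings were chosen after seeing the data. Over the alternatives, 5546 values of named genes kept their side of the threshold without a reversal, 198 passed where they had not, 426 no longer passed and 13 reversed. For list tests these were 642, 22, 33 and 3. A reversal is a change of direction where either value passed or, for genes, where both exceeded their error. Other changes of direction were counted as kept. Of 95 named genes past the threshold, all 95 kept their direction in the columns as deposited and with only the groups compared in the fit, and 56 and 47 passed there. The cause was not tested for any change below, except where the setting's construction gives it (fewer mice, fewer genes tested).

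Numbers of genes past the threshold are given in the order 5xFAD against WT in cortex, hippocampus and cerebellum. DESeq2 gave 550, 858 and 391, limma on cell means 557, 509 and 15, and no filter on low counts 190, 327 and 98. Without the filter the errors shrank (Apoe in hippocampus 5.09 ± 0.10 against 5.08 ± 1.00), so those counts are not comparable. Voom gave 362 in hippocampus and 66 in cerebellum. Only genes in at least 10% of cells gave 93 in cortex and 19 in cerebellum, and only the groups compared 25 in cortex and 0 in cerebellum. In cerebellum the columns as deposited gave 0, thinned cells 14 and no wells of plate columns 1 and 2 gave 3.

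For hippocampus against cerebellum in 5xFAD, DESeq2 gave 394, voom 270, no filter 107, 10% of cells 59, only the groups compared 5 and the columns as deposited 0. For hippocampus against cortex in WT, DESeq2 gave 384, no filter 43, limma on cell means 11, voom 5 and mouse as a block 5. For cerebellum against cortex in WT, DESeq2 gave 602, limma on cell means 217, no filter 215, 10% of cells 93, thinned cells 89, mouse as a block 26 and only the groups compared 13. For hippocampus against cerebellum in WT, DESeq2 gave 797, limma on cell means 400, no filter 233, no wells of plate columns 1 and 2 gave 40 and only the groups compared 13.

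For cerebellum against cortex in 5xFAD, DESeq2 gave 318, voom 99, no filter 77, limma on cell means 72, DESeq2 size factors 5, mouse as a block 4, no clusters led by other cell types 3, no wells of plate columns 1 and 2 gave 2 and the columns as deposited 1. For hippocampus against cortex in 5xFAD, DESeq2 gave 282, limma on cell means 112, no filter 41, voom 38, thinned cells 14, the columns as deposited 0 and only the groups compared 0. The combination that cancels plates gave 500 with DESeq2, 167 with limma on cell means, 110 without a filter, 43 with voom, 7 without plate columns 1 and 2, and 0 in the columns as deposited, with the stricter cell filter and with thinned cells.

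The difference in genotype effect between hippocampus and cerebellum had 622 genes with DESeq2, 186 without a filter, 137 with voom, 127 with limma on cell means, 94 in 10% of cells and 18 in the columns as deposited. Between cortex and cerebellum it had 393 with DESeq2, 95 without a filter, 7 without plate columns 1 and 2 and 3 with limma on cell means. Of 35 list tests past the threshold at the preset correlation, 19 passed with an estimated correlation. Limma on cell means moved the median of all genes in cortex from -0.0881 to 0.203.

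Leaving out 1 mouse at a time gave 29 to 46 genes in cortex, 113 to 140 in hippocampus and 1 to 10 in cerebellum. It gave 7 to 38 for hippocampus against cerebellum in 5xFAD, 0 to 2 for hippocampus against cortex in WT, 32 to 54 for cerebellum against cortex in WT and 39 to 76 for hippocampus against cerebellum in WT. It gave 2 to 9 for cerebellum against cortex and 3 to 5 for hippocampus against cortex in 5xFAD, 1 to 14 for the combination that cancels plates, and 18 to 64 and 8 to 15 for the differences in genotype effect of hippocampus and of cortex from cerebellum. Differences in the share of panel cells ran from 25.5 to 29.4 points in cortex, 54.5 to 61.8 in hippocampus, 5.53 to 14.7 in cerebellum and 36.0 to 45.4 between hippocampus and cerebellum in 5xFAD; with 1 mouse fewer the smallest possible exact p is 0.0667 or 0.1 in hippocampus. The share in cerebellum differed by 11.2 points with at least 4 genes and by -2.96 points in the columns as deposited.

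These values reversed. Without clusters led by other cell types, MHC class II went to 0.20 in hippocampus and to 0.34 between hippocampus and cerebellum in 5xFAD, the clearance program to 0.30 in the latter, H2-Aa to 3.30 in cortex and 2.98 in hippocampus, and H2-Ab1 to 1.88 in cortex. With limma on cell means, H2-Ab1 went to 0.69 in cortex, Ptk2b to 0.96 and Apoe to 2.35 in cerebellum, where Apoe passed (adjusted p = 0.026), and Ctsa to 0.54 between hippocampus and cortex in WT. Ciita went to 3.38 in hippocampus in the columns as deposited. Leaving out 1 mouse gave -4.96 to 3.01 for H2-Aa and -3.63 to 1.47 for H2-Ab1 in cortex, -4.16 to 2.62 for H2-Aa in hippocampus, -2.95 to 8.95 for Gpnmb in cerebellum and -9.78 to 6.23 for Cxcl10 between hippocampus and cerebellum in 5xFAD.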

Other observations

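The comparison of 5xFAD cortex with WT cerebellum, the set of 14 genes for dividing cells with its minimum of 6, and the Pearson and permutation forms of the Slc34a2 relation were chosen only after the results were seen.

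A cluster led by markers of other cell types held 36 of the 1041 cells: 21 in 5xFAD cerebellum (10.9%, 3 mice), 13 in WT cerebellum (8.02%, 3 mice), 1 in WT cortex, 1 in WT hippocampus and 0 in 5xFAD cortex and hippocampus. At least 3 markers of macrophages at brain borders were detected in 15, 13, 1 and 1 of them, and at least 3 neutrophil markers in 9 of those in 5xFAD cerebellum; the sort used CD206, Ly6C and Ly6G. Mean Apoe in these cells was 26690 CPM in 5xFAD cerebellum, 52000 CPM in WT cerebellum and 46300 and 35700 CPM in the single wells of WT cortex and WT hippocampus. In the other cells of these groups it was 2795, 666.4, 147.9 and 160.2 CPM. A further cluster, kept in the main fit, held 135 cells at a median of only 37489 reads in genes. It was uneven between the genotypes, with 37 cells of WT and 9 of 5xFAD cortex. In hippocampus it had 14 of WT and 31 of 5xFAD, and in cerebellum 29 of WT and 15 of 5xFAD.

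At least 6 of 14 genes of dividing cells were detected in 5 of 1041 cells, 4 of them in 5xFAD cerebellum and 1 in WT hippocampus. Of the 4, 3 came from mouse 3, lay in the cluster led by markers of other cell types and had 9 or 10 neutrophil markers. Without that cluster the cell cycle list in cerebellum had a median of 1.99, with 19 of 24 genes positive instead of 24 of 26 (adjusted p = 0.000436, and 0.172 with an estimated correlation).

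On their shared plate, 5xFAD cortex against WT cerebellum gave 45 genes (edgeR; 39 higher and 6 lower), a comparison that mixes genotype and region. The disease-associated microglia (median 0.76), lysosome (0.50) and homeostatic lists (0.20) were higher in 5xFAD cortex. Their largest camera adjusted p was 1.87e-11, and 0.00123 with an estimated correlation. Interferon response (-0.52), MHC class II (-1.87) and the clearance program (-2.23) were lower. These calls were lost with an estimated correlation (adjusted p = 0.335, 0.069 and 0.159). P2ry12 was higher by 0.65 ± 0.08 and Fcrls by 1.46 ± 0.10.

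Median Slc34a2 was 2876 CPM in WT cortex and 2905 CPM in WT hippocampus. The ratio of Slc34a2 to ERCC reads was 0.862, 0.482 and 0.459 in the blanks of the plates of WT cortex, 5xFAD cortex and 5xFAD hippocampus. Pearson's r of Slc34a2 with ERCC reads per gene read ran from 0.466 to 0.794 over the 6 groups (permutation p = 1e-05 in each, the smallest that 100000 permutations can give) and from 0.386 to 0.768 without the 2 farthest wells; for 7 other genes rho was at most 0.173.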
